A study of Homo sapiens with 48 samples.

How the data were processed

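Total RNA of 48 samples of PC-3 and 22Rv1 cells was hybridized to Illumina bead arrays, per the labels, after 24 h at 37 °C in RPMI-1640 in a hypoxia chamber at 5, 2, 1, 0.5, 0.2 or 0% O2 or in normoxia. RNA was prepared by miRNeasy, per the labels. The series description names 5 levels, and the sample titles and the protocol also give 0%. The deposited intensity table holds a mean bead intensity per probe and array, exported with BeadStudio 3.1.3.0 per the submitters' processing notes, and its values show no background subtraction. A deposited detection p-value stands beside each intensity and moves in steps that imply 770 negative control probes. A further deposited table gives linear intensities whose normalization is not given in the sources used here. Its sorted columns are nearly equal, as after quantile normalization, and it served as an alternative. Matching the columns of both tables by their values, 46 arrays agreed in label and 2 were exchanged, the hypoxia and normoxia arrays of 22Rv1 replicate 2 at 0.2% O2. The labels of the intensity table were used, with the other labels as an alternative. No pair of columns was identical.

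Detection at p under 0.01 was reached by 13750 to 16494 probes per array (median 15405), 13750 to 16121 in PC-3 and 13995 to 16494 in 22Rv1, and the median intensity of an array was 84.2 to 117 (median 98.4). Values from dim probes are therefore compressed toward background. A probe was kept when detected on at least 2 arrays, and of several probes for a symbol the brightest was used. Of 47323 probes 3270 had no symbol, and 16438 gene symbols were tested, called genes here. Of these, 11119 symbols were current in the human gene table and 2030 were reached through a synonym. Genes are printed under the symbol of the array with the current symbol at first mention where it differs. A genome build for the array is not given in the sources used here, so no positions are given, and Y-linked genes and XIST are not reported.

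Background was corrected with the normal-exponential model of limma 3.58.1 (neqc, offset 16, negative control level taken from the detection p-values), followed by quantile normalization and log2, in R 4.3.3 with the data.table package (version 1.17.8). A linear model with a mean for each of the 24 groups was fitted in limma with moderated variances and a variance trend, with 24 residual degrees of freedom (32.3 with the prior). The comparisons were hypoxia against its own control at each level, the mean over the 6 levels, the trend per rank step from 5 to 0%. They further included the difference of the mean effect between lines (22Rv1 minus PC-3), the lines in normoxia, and an F-test among the control groups of a line. P-values were adjusted within each comparison by the Benjamini-Hochberg method, with a threshold of 0.05. Where the group compared against was not detected on any array, the fold was taken against the floor and is given as at least that value. For means, trends and line differences no size is given where fewer than 6 of the 12 arrays on the lower side detected the gene. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

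Of 34 gene lists written before the data were examined, 33 had at least 5 measured genes and were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry. Counts within a list use the adjustment over all genes, with a further count adjusted over the list alone. They include members that a line did not detect. AK4, CDK1 and KDM5A were not matched on the array. The comparisons, the lists, the other settings to try and the rule for named genes were all fixed before the data were examined. The rule named, for the mean over levels, the 12 largest rises and falls past the threshold with the same sign in every pair. It named for each level the 3 largest each way with the same sign in both pairs, and for the trend 6 each way. For the line difference and for normoxia 8 each way were named, together with KLK2 and KLK3. All HIF core targets were named, and for each list the 4 members with the largest absolute mean change in either line. Unannotated symbols were passed over, and 3 of the genes and 1 of the lists are not reported here.

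Whether the replicate numbers pair the samples was checked on each array's deviation from its group mean. Between the hypoxia and control groups of a level these deviations correlated by 0.326 to 0.471 in PC-3 (mean 0.397, against controls of other levels 0.316) and 0.180 to 0.447 in 22Rv1 (mean 0.286, against controls of other levels 0.156). All were over 0.1, so a replicate block by pair was run beside the unblocked model. The other alternatives were array weights, no background correction, median centring in place of quantile normalization, the other table, no filter or a filter of 12 arrays, and the mean of probes. They further included each line alone, the 12 controls of a line pooled, a block over the line, no variance trend, log2 oxygen or 5 levels for the trend and the mean over 5 levels, and leaving out each array. The other labels of the 2 doubted arrays, in both tables, and their removal were added after seeing the data. On simulated data with 50 genes per size, the PC-3 0% comparison recovered 12, 76, 100 and 100% of changes of 0.5, 1, 2 and 3 (log2) with 5.26% false calls. The 22Rv1 mean recovered 20, 92, 100 and 100% of changes of 0.25, 0.5, 1 and 1.5 with 6.59% false calls. The PC-3 trend recovered 2, 62, 100 and 100% of slopes of 0.1, 0.2, 0.4 and 0.6 with 4.35% false calls. The simulated noise was independent between arrays, unlike the correlated deviations above, and fewer genes changed than were called in these comparisons. Recovery and false calls on the real data can therefore differ.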

Results

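Gene expression was measured on Illumina bead arrays of 47323 probes in PC-3 and 22Rv1 cells, both human prostate cancer lines, after culture at a low oxygen level or in normoxia (95% air). PC-3 derives from a bone metastasis and 22Rv1 from a xenograft. Each line was kept at 5, 2, 1, 0.5, 0.2 or 0% O2, and every level had its own normoxia control. With 2 replicates of each condition there were 48 arrays in 24 groups of 2. Between 13750 and 16494 probes were detected per array (29.1 to 34.9% of the probes), and 16438 gene symbols were tested, each represented by a single probe. They are called genes here, although a gene under an old and a current symbol, as HSPC111 and NOP16, counts more than once. Changes are log2 differences, hypoxia minus normoxia, with the standard error of the fit (SE). The number of arrays limits the precision: a change at a single level compares 2 arrays with 2, and a mean over the 6 levels compares 12 with 12. Nothing states that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical. The tables disagree about 2 arrays, the hypoxia and normoxia arrays of 22Rv1 replicate 2 at 0.2% O2, and the values here follow the intensity table.

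The first question was which genes changed in PC-3 on the mean over the oxygen levels. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 15.1-fold averaged over the levels (log2 3.91 ± 0.15, SE, n = 12 arrays per condition, adjusted p = 5.3e-19). Its level went from a mean log2 intensity of 7.31 ± 0.46 (SD) in normoxia to 11.22 ± 1.36 in hypoxia. The stress-response gene NDRG1 rose by 2.24 ± 0.14. DDIT4, an inhibitor of mTORC1 signalling, rose by 2.08 ± 0.13 and the vasodilator peptide gene ADM by 2.04 ± 0.15. The calcium channel gene ITPR1 (2.02 ± 0.09) and the glucose transporter SLC2A1 (1.85 ± 0.09) rose as well. So did the metalloprotease ADAM8 (1.85 ± 0.10) and ANKRD37 (1.76 ± 0.11). C10orf10 (current symbol DEPP1), the epithelial sodium channel subunit SCNN1G, PPFIA4 and the kisspeptin receptor KISS1R also rose. They were detected on 4, 2, 2 and 3 of 12 normoxia arrays, so no size or rank is given for them. HIF1A, which encodes the oxygen-regulated subunit of hypoxia-inducible factor 1, had the largest fall (−1.21 ± 0.09, adjusted p = 1.5e-12), from 8.15 in normoxia to 6.94. The rule for naming required each of these genes to move the same way in 12 of 12 hypoxia and control pairs. In all, 3946 genes changed in limma at an adjusted p under 0.05, of which 1755 rose and 2191 fell. Only 93 of them changed at least 2-fold, 92 upward and HIF1A downward. A gene can pass on this mean without a change at every level, and with 0% left out 2805 genes passed.

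The other 11 of the 12 largest falls with the same sign in every PC-3 pair lay between −0.90 and −0.74. They were C14orf126 (DTD2, −0.90), CD3EAP (POLR1G, an RNA polymerase I subunit, −0.87), HSPBAP1 (−0.85), TAF9L (TAF9B, −0.85), RAB3IL1 (−0.84), C1orf163 (COA7, −0.81), the protocadherin PCDH20 (−0.80), FLJ38482 (−0.80), FBXO4 (−0.78), the helix-loop-helix inhibitor ID3 (−0.74) and TIPIN, which protects replication forks (−0.74). The count of 3946 was 2286 when arrays were centred on their medians in place of quantile normalization, 957 of them higher and 1329 lower.

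The same question in 22Rv1 gave larger values. ADM rose 19.1-fold over the levels (log2 4.25 ± 0.15, SE, n = 12 arrays per condition, adjusted p = 1.5e-21). The metallothionein MT3 was not detected on any normoxia array and was at least 11.4-fold higher in hypoxia (adjusted p = 1e-28), PPFIA4 at least 10.5-fold and ANKRD37 at least 10.7-fold. The transcriptional repressor BHLHB2 (BHLHE40) rose by 3.98 ± 0.11, and the fructose-2,6-bisphosphate enzyme PFKFB4 by 3.83 ± 0.09. NDUFA4L2, which lowers complex I activity, rose by 3.44 ± 0.12, DDIT4 by 3.43 ± 0.13 and NDRG1 by 3.34 ± 0.14. The mitophagy receptor BNIP3 rose by 2.97 ± 0.07 and the lactate exporter SLC16A3 by 2.88 ± 0.08. In all, 7007 genes changed (3253 higher and 3754 lower), and 301 of them changed at least 2-fold, 256 upward and 45 downward. Under median centring 5663 genes changed, 2089 higher and 3574 lower. With 0% left out the mean called 6296 genes.

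Genes that act in DNA synthesis were among the largest falls in 22Rv1. The DNA polymerase epsilon subunit POLE2 fell by 1.59 ± 0.10, CDCA7 by 1.51 ± 0.13 and the S phase cyclin CCNE2 by 1.45 ± 0.12. UHRF1, which maintains DNA methylation, fell by 1.35 ± 0.14, the phosphatase CDC25A by 1.30 ± 0.13 and the ribonucleotide reductase subunit RRM2 by 1.27 ± 0.13. The histone chaperone subunit CHAF1B (−1.26 ± 0.10), TIPIN (−1.25 ± 0.13), GINS2 (−1.25 ± 0.11) and MCM10 (−1.24 ± 0.12), which act in replication, followed, together with MIR1978 (−1.35 ± 0.08) and FLJ12684 (no size given, detected on 5 of 12 hypoxia arrays). In this line too the rule named for the mean only genes that moved the same way in 12 of 12 pairs.

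**Figure D1:**
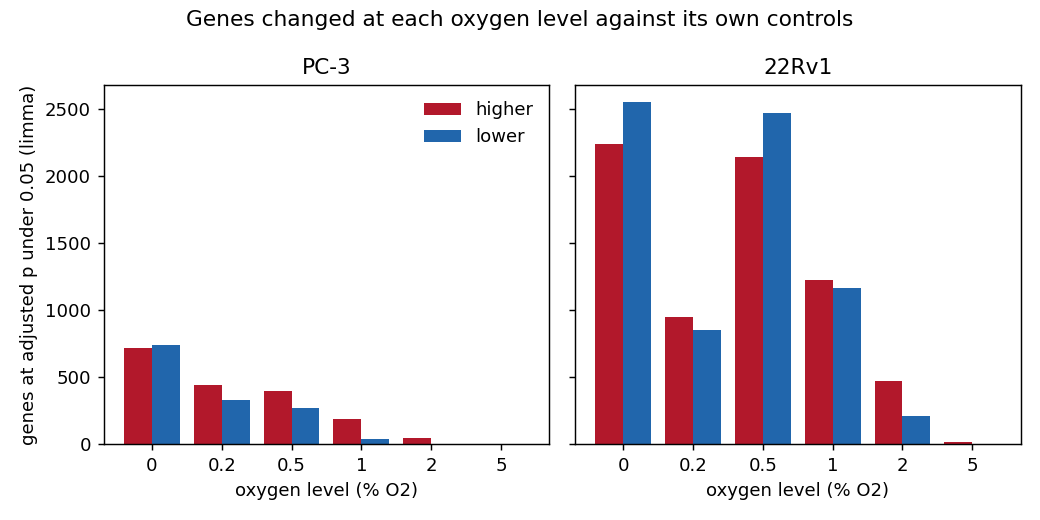
Number of genes past an adjusted p of 0.05 at each oxygen level (x axis, % O2), higher (red bars) and lower (blue bars) in hypoxia, in PC-3 (left) and 22Rv1 (right), 2 hypoxia against 2 normoxia arrays per level. PC-3 went from 1456 genes at 0% to 1 gene at 5%, and 22Rv1 from 4794 to 15 with fewer at 0.2% (1801) than at 0.5% (4611).

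Each level was then set against its own controls to ask how strong the response was at that level. In PC-3 at 0% O2, 1456 genes changed, 715 higher and 741 lower. ANGPTL4 (5.60 ± 0.37, n = 2 against 2), C10orf10 (3.60 ± 0.32) and SCNN1G (at least 7.96-fold) led the rises. HIF1A (−2.36 ± 0.21), C1orf163 (at least 3.26-fold lower) and ID3 (−1.48 ± 0.22) fell. At 0.2% there were 778 genes (445 higher, 333 lower). Among them were ANGPTL4 at 4.64 ± 0.37, SCNN1G at least 5.64-fold and C10orf10 at least 6.47-fold higher, and HIF1A (−1.65 ± 0.21), HSPBAP1 (−1.31 ± 0.20) and the neurotrophin BDNF (−1.19 ± 0.26) lower. At 0.5%, 670 genes changed (397 higher, 273 lower). These had ANGPTL4 (4.97 ± 0.37), NDRG1 (2.80 ± 0.35) and SCNN1G (at least 3.83-fold) higher and HIF1A (−1.52 ± 0.21), C14orf126 (−1.25 ± 0.28) and the ciliary gene BBS4 (−1.11 ± 0.25) lower. At 1% there were 230 (191 higher, 39 lower). These included ANGPTL4 (3.84 ± 0.37), NDRG1 (2.41 ± 0.35), PPFIA4 (at least 2.85-fold higher), FLJ38482 (−0.97 ± 0.20), HIF1A (−0.94 ± 0.21) and TAF9L (−0.90 ± 0.22). At 2% all 48 changed genes were higher, led by ANGPTL4 (2.96 ± 0.37), NDRG1 (2.01 ± 0.35) and PPFIA4 (at least 2.59-fold). At 5% the only gene past the threshold was the anchoring fibril collagen COL7A1 (1.51 ± 0.21, adjusted p = 0.00067), with 682 genes at an unadjusted p under 0.05.

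These PC-3 counts depended on single arrays, on the pairing and on the normalization. With each hypoxia array blocked with its same-numbered control they were 2647, 1770, 1642, 682, 213 and 57 from 0 to 5%. Under median centring they were 524 at 0%, 212 at 0.2% and 44 at 1%. At 0.5% that setting gave 884 genes, 73 higher and 811 lower, so the balance of called directions at that level depends on the normalization. The median of all genes was −0.29 there, since centring leaves differences in the range of intensities between arrays. Hypoxia replicate 2 of this level detected the fewest probes of all arrays (13750). Whether that array made the 811 falls was not tested. Leaving out hypoxia replicate 1, hypoxia replicate 2, normoxia replicate 1 or normoxia replicate 2 of a level, in that order, gave 642, 799, 904 and 574 at 0%, 419, 418, 267 and 474 at 0.2% and 364, 369, 252 and 331 at 0.5%. It gave 63, 107, 92 and 58 at 1%, 40, 10, 11 and 20 at 2% and 2, 1, 0 and 3 at 5%. Without a single array of their level, the calls ended for BDNF at 0.2% (−0.87, adjusted p = 0.18) and for C14orf126 (−0.98, adjusted p = 0.14) and BBS4 (−0.97, adjusted p = 0.13) at 0.5%. At 1% they ended for FLJ38482 (−0.76, adjusted p = 0.25), HIF1A (−0.72, adjusted p = 0.34) and TAF9L (−0.70, adjusted p = 0.50). At 2% they ended for NDRG1 and for PPFIA4 (no size given, its controls at that level were not detected). At 5%, without normoxia replicate 1, the call ended for COL7A1 (1.13).

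In 22Rv1 at 0% O2, 4794 genes changed (2242 higher, 2552 lower), 1519 of them at least 2-fold. BHLHB2 (5.82 ± 0.27), ADM (5.74 ± 0.36) and ANKRD37 (at least 30.8-fold) led the rises, and the centromere histone gene CENPA (−2.73 ± 0.17), CCNF (−2.66 ± 0.15) and the mitotic cyclin CCNA2 (−2.66 ± 0.17) the falls. At 0.2% there were 1801 genes (950 higher, 851 lower). These had MT3 at least 26.6-fold, ADM (4.80 ± 0.36) and PPFIA4 at least 13.2-fold higher and POLE2 (−1.58 ± 0.26), FLJ12684 (−1.53 ± 0.23) and CDCA7 (−1.53 ± 0.31) lower. At 0.5% there were 4611 (2140 higher, 2471 lower). These had ADM (5.33 ± 0.36), MT3 at least 24.0-fold and BHLHB2 (4.71 ± 0.27) higher and UHRF1 (−2.99 ± 0.34), CCNE2 (−2.82 ± 0.30) and the replication clamp PCNA (−2.70 ± 0.49) lower. At 1% there were 2389 (1224 higher, 1165 lower). These had MT3 at least 24.0-fold, ADM (4.82 ± 0.36) and PPFIA4 at least 17.6-fold higher and POLE2 (−2.05 ± 0.26), CCNE2 (−1.94 ± 0.30) and the helicase BLM (at least 2.71-fold) lower. At 2% there were 680 (469 higher, 211 lower). These had ADM (3.72 ± 0.36), PPFIA4 at least 9.23-fold and PFKFB4 (3.66 ± 0.22) higher and MIR1978 (−1.23 ± 0.19), the metallothionein MT1G (−1.18 ± 0.33) and WDR62 (−1.11 ± 0.24) lower. At 5% 14 genes were higher, led by PFKFB4 (2.02 ± 0.22), BNIP3 (2.00 ± 0.17) and DDIT4 (1.91 ± 0.31), and MIR1978 was lower (−0.92 ± 0.19).

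The pair block gave 3272 genes at 0.2%, 3944 at 1%, 1969 at 2% and 50 at 5% in 22Rv1. Median centring gave 2739 at 0%, 638 at 0.2%, 2595 at 0.5%, 1063 at 1%, 232 at 2% and 2 at 5%. With the 2 doubted arrays labelled as in the other table limma called 0 genes at 0.2% (712 at an unadjusted p under 0.05), 34 at 2% and 0 at 5% (542 at an unadjusted p under 0.05). Left-out arrays moved the counts to 430 (hypoxia replicate 1), 1064 (normoxia replicate 2) or 3249 (hypoxia replicate 2) at 0.2% and 2015 (hypoxia replicate 1) at 0.5%. They moved them to 1079 (normoxia replicate 1), 1149 (hypoxia replicate 2) or 1487 (normoxia replicate 2) at 1%. Without hypoxia replicate 1, hypoxia replicate 2, normoxia replicate 1 or normoxia replicate 2 the counts were 175, 328, 446 and 321 at 2% and 3, 35, 8 and 5 at 5%. Left-out arrays also ended the calls of CDCA7 at 0.2% (−0.59, adjusted p = 0.27), MT1G (−1.04, adjusted p = 0.29) and WDR62 (−0.97, adjusted p = 0.12) at 2%, and DDIT4 (1.28, adjusted p = 0.68) and MIR1978 (−0.71, adjusted p = 0.81) at 5%. Between the 0.5% and 0.2% effects themselves limma called 0 genes in 22Rv1 (1436 at an unadjusted p under 0.05, 18 with the pair block, 1509 with the 12 controls pooled) and 0 in PC-3 (379 at an unadjusted p under 0.05). Of 33 lists 8 passed camera on this comparison in 22Rv1 and 0 in PC-3, and 0 passed with an estimated correlation in either line.

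HIF core targets, genes with well-described binding of hypoxia-inducible factors, rose in both lines. Over the levels 21 of 21 measured targets rose in PC-3 (21 adjusted over the list alone, median 1.16, camera adjusted p = 2.2e-36). In 22Rv1 20 of 21 rose (20 adjusted over the list alone, median 2.56, camera adjusted p = 3.8e-32). By level, from 0 to 5%, the median in PC-3 was 1.59, 1.51, 1.42, 1.11, 0.97 and 0.53 with 19, 17, 17, 13, 9 and 0 targets past the test. In 22Rv1 it was 3.64, 2.87, 2.96, 2.77, 2.14 and 0.89 with 20, 20, 20, 20, 18 and 9. Adjusted over the list alone, 20, 20, 20, 19, 18 and 8 passed in PC-3, and 20, 20, 20, 20, 20 and 14 in 22Rv1. At 5% in PC-3 the list passed camera (adjusted p = 3.6e-13) but not with an estimated correlation (adjusted p = 0.080).

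**Figure D2:**
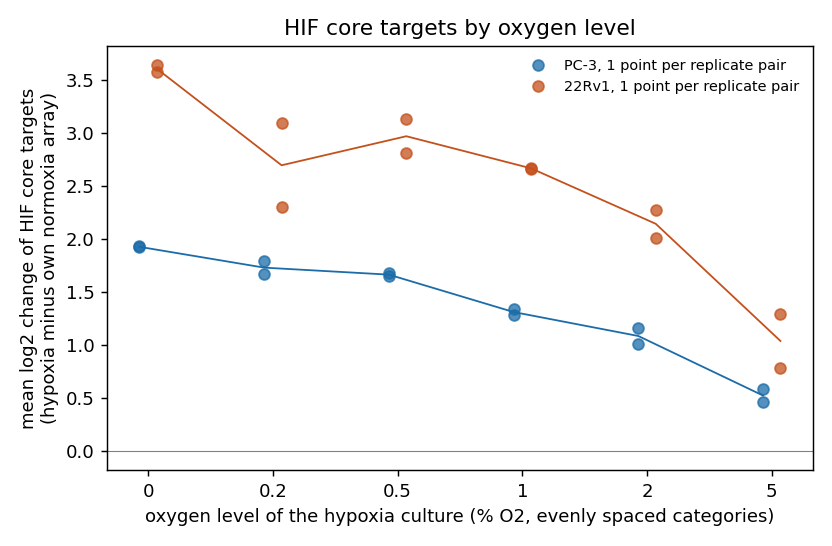
Mean log2 change of the measured HIF core targets (y axis) at each oxygen level (x axis, % O2 as evenly spaced categories), as the difference between each hypoxia array and its own normoxia array, with 1 point per replicate pair and lines through the means. 22Rv1 lies above PC-3 at 0%, where the list medians were 3.64 and 1.59, and both lines come closest at 5%.

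VEGFA, the main angiogenic growth factor, rose by 1.10 ± 0.12 in PC-3 and 2.37 ± 0.12 in 22Rv1 (SE, n = 12 arrays per condition). The other targets rose by 1.85 ± 0.09 and 2.32 ± 0.09 (SLC2A1), 1.08 ± 0.07 and 2.97 ± 0.07 (BNIP3), and 0.99 ± 0.11 and 2.84 ± 0.11 (P4HA1, a collagen prolyl hydroxylase) in PC-3 and 22Rv1. The changes were 0.85 ± 0.15 and 2.24 ± 0.15 (JMJD1A, current symbol KDM3A), 0.85 ± 0.11 and 1.30 ± 0.11 (MXI1), 0.98 ± 0.11 and 3.98 ± 0.11 (BHLHB2), and 3.91 ± 0.15 and 2.56 ± 0.15 (ANGPTL4) in PC-3 and 22Rv1. Rises of 0.89 ± 0.11 and 1.83 ± 0.11 were measured for the oxidoreductase ERO1L and 1.24 ± 0.09 and 1.75 ± 0.09 for INSIG2. They were 1.16 ± 0.12 and 1.73 ± 0.12 for ANKZF1, 1.23 ± 0.24 and 1.96 ± 0.24 for FAM162A and 0.17 ± 0.03 and 0.998 ± 0.03 for lactate dehydrogenase A (LDHA). CA9, carbonic anhydrase IX, was detected on 5 of the 12 hypoxia arrays of PC-3 and passed the test there (adjusted p = 0.00054), but on no array of 22Rv1. The LDHA call in PC-3 ended under median centring (0.20, adjusted p = 0.13).

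Glycolysis genes rose with them, and SLC2A1, PFKFB3, PFKFB4, LDHA and SLC16A3 are members of both lists. In PC-3 21 of 22 measured genes rose and 1 fell (the same counts adjusted over the list alone, median 0.68, camera adjusted p = 3.2e-29). In 22Rv1 21 rose and 0 fell (21 and 0 adjusted over the list alone, median 1.26, camera adjusted p = 1.7e-28). SLC16A3 rose by 0.90 ± 0.08 and 2.88 ± 0.08 and hexokinase HK2 by 1.06 ± 0.11 and 2.80 ± 0.11. PFKFB3 rose by 1.36 ± 0.07 and 2.68 ± 0.07 and PFKFB4 by 1.68 ± 0.09 and 3.83 ± 0.09 in PC-3 and 22Rv1. Of the HIF pathway and oxygen sensors, 5 of 14 rose and 1 fell in PC-3 (5 and 1 adjusted over the list alone, median 0.12, camera adjusted p = 0.028, adjusted p = 0.064 with an estimated correlation). In 22Rv1 3 rose and 2 fell (3 and 2 adjusted over the list alone, median 0.11, camera adjusted p = 0.11). The oxygen sensor EGLN1 rose by 1.01 ± 0.09 and 1.601 ± 0.09. CITED2, which competes with HIF1A for its coactivators, rose by 0.84 ± 0.08 and 1.08 ± 0.08, and the ubiquitin ligase SIAH2 by 0.55 ± 0.08 and 0.84 ± 0.08. HIF1A was −1.21 ± 0.09 and −0.42 ± 0.09. The 22Rv1 call for HIF1A ended when its probes were averaged (−0.19, adjusted p = 0.20).

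Histone demethylases, angiogenic factors and matrix genes contained further risers. These lists share JMJD1A, then VEGFA, ADM and ANGPTL4, and P4HA1, in that order, with the HIF core targets. Among 12 histone demethylases, 4 rose in PC-3 (5 adjusted over the list alone, median 0.16, camera adjusted p = 0.0050, adjusted p = 0.20 with an estimated correlation). In 22Rv1 7 rose (7 adjusted over the list alone, median 0.37, camera adjusted p = 0.00013, adjusted p = 0.064 with an estimated correlation). In PC-3 and 22Rv1 the values were JMJD1A at 0.85 and 2.24, KDM5B at 0.48 ± 0.11 and 1.18 ± 0.11 and JMJD2B (KDM4B) at 0.67 ± 0.11 and 1.05 ± 0.11. KDM6B rose by 0.86 ± 0.14 in 22Rv1 and missed the threshold in PC-3 (adjusted p = 0.072, adjusted p = 0.0089 with the pair block), where 0 of 12 normoxia and 3 of 12 hypoxia arrays detected it. Of 14 angiogenic and secreted factors, 9 rose in PC-3 (9 adjusted over the list alone, median 0.69, camera adjusted p = 3.0e-11). In 22Rv1 10 rose (10 adjusted over the list alone, median 0.86, camera adjusted p = 2.0e-08). The glycoprotein hormone gene STC1 rose in PC-3 (no size given, detected on 4 of 12 normoxia arrays) and was at least 2.47-fold higher in 22Rv1. Of 14 collagen modification and matrix genes, 9 rose in PC-3 (9 adjusted over the list alone, median 0.68, camera adjusted p = 4.6e-11). In 22Rv1 6 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.16, camera adjusted p = 9.8e-05). In PC-3 and 22Rv1 P4HA2 rose by 1.35 ± 0.10 and 2.59 ± 0.10 and PLOD2, a lysyl hydroxylase, by 1.03 ± 0.08 and 2.17 ± 0.08. The collagen crosslinker LOX was at least 1.57-fold and 2.98-fold higher in the same order.

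**Figure D3:**
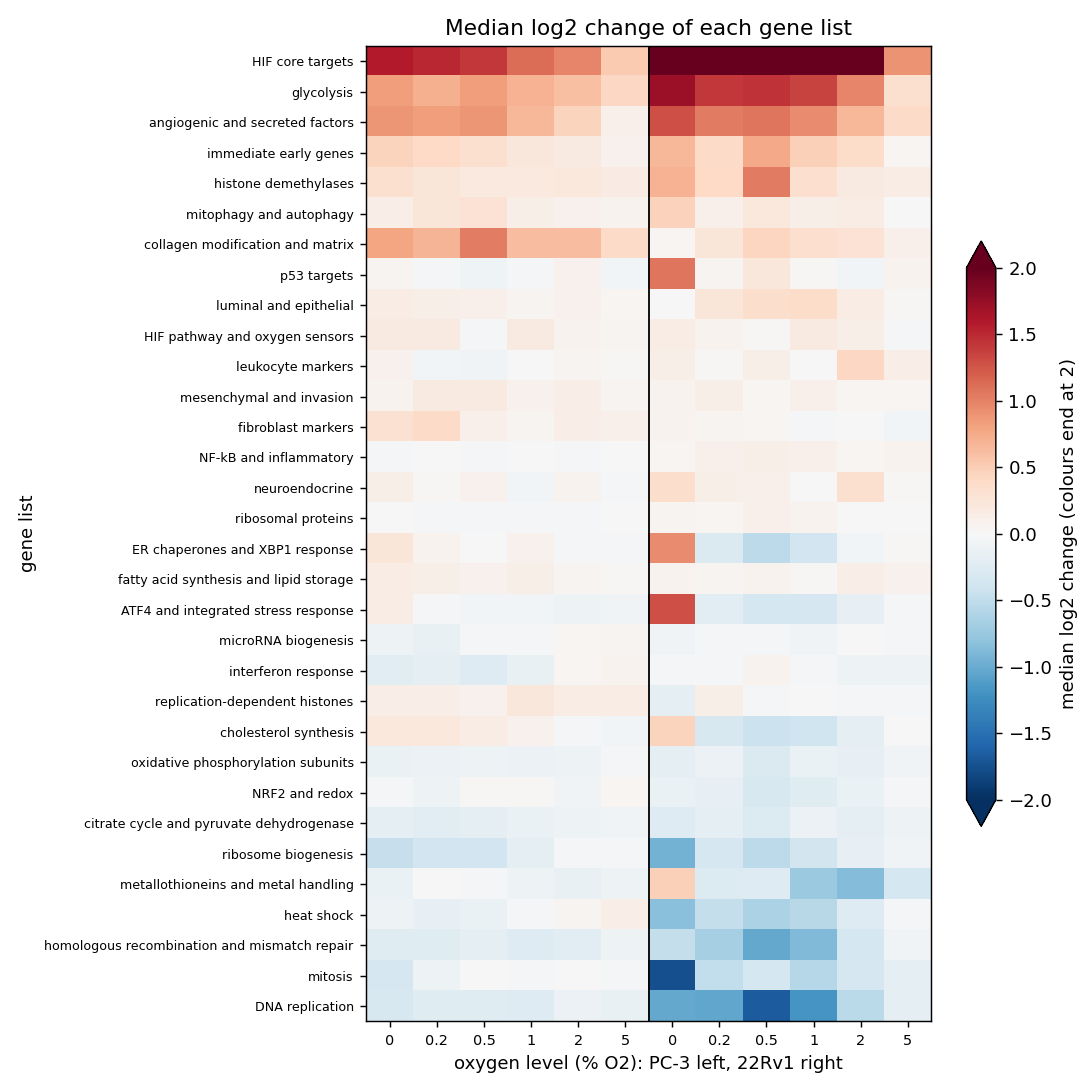
Median log2 change (colour, blue lower and red higher in hypoxia) of each gene list with at least 5 measured genes (y axis) at each oxygen level (x axis, % O2), PC-3 on the left and 22Rv1 on the right of the line. HIF core targets stand at the top of the scale, and in 22Rv1 the mitosis list reaches −1.76 and the ATF4 list 1.29 at 0%.

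Proliferation genes fell in 22Rv1, and fewer of them passed in PC-3. Of 31 DNA replication genes, 27 fell in 22Rv1 (27 adjusted over the list alone, median −0.94, camera adjusted p = 4.3e-19). In PC-3 14 fell (16 adjusted over the list alone, median −0.23, camera adjusted p = 1e-05, adjusted p = 0.26 with an estimated correlation). Values were POLE2 at −1.59 and −0.54, CCNE2 at −1.45 and −0.26 (adjusted p = 0.14 in PC-3), RRM2 at −1.27 and −0.37 and GINS2 at −1.25 and −0.37 in 22Rv1 and PC-3. All 27 measured mitosis genes fell in 22Rv1 (27 adjusted over the list alone, median −0.62, camera adjusted p = 1.3e-16). They included CCNA2 (−0.92 ± 0.07), the survivin gene BIRC5 (−0.80 ± 0.05), the kinetochore gene NDC80 (−0.77 ± 0.14) and Aurora kinase B (AURKB, −0.76 ± 0.07). In PC-3 2 of the 27 passed (0 adjusted over the list alone, median −0.09, camera adjusted p = 0.077). Of 22 genes of homologous recombination and mismatch repair, 18 fell in 22Rv1 (18 adjusted over the list alone, median −0.60, camera adjusted p = 7.6e-10). In PC-3 12 fell (13 adjusted over the list alone, median −0.21, camera adjusted p = 0.00076, adjusted p = 0.16 with an estimated correlation). In 22Rv1 and PC-3 BLM was at −1.15 and −0.31, the exonuclease EXO1 at −1.14 and −0.34 and BRCA1 at −0.90 and −0.34. XRCC3 was −0.89 and −0.12 (adjusted p = 0.40 in PC-3). Among 20 p53 targets, 8 rose and 2 fell in 22Rv1 (9 and 2 adjusted over the list alone, median 0.155, camera adjusted p = 0.00645). In PC-3 3 rose and 5 fell (3 and 5 adjusted over the list alone, median 0.01, camera adjusted p = 0.74). The cell cycle inhibitor CDKN1A rose by 0.93 ± 0.11 in 22Rv1 and 0.78 ± 0.11 in PC-3, and TP53INP1 by 0.89 ± 0.10 and 0.37 ± 0.10. GADD45A rose by 0.79 ± 0.13 and BTG2 by 0.77 ± 0.08 in 22Rv1.

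Averaged over the levels, the ATF4 and ER chaperone lists held genes of both directions. Of 26 genes of the ATF4 and integrated stress response, 7 rose and 6 fell in 22Rv1 (7 and 6 adjusted over the list alone, median −0.01, mean 0.16, camera adjusted p = 0.445). In PC-3 5 rose and 4 fell (6 and 5 adjusted over the list alone, median −0.03, mean 0.06, camera adjusted p = 0.62). GDF15, a stress-induced cytokine, rose by 2.01 ± 0.18 in 22Rv1 and was 0.45 ± 0.18 in PC-3 (adjusted p = 0.070, adjusted p = 0.00033 with the pair block). STC2 rose by 1.10 ± 0.06 and 1.22 ± 0.06, and VLDLR by 1.22 ± 0.10 in 22Rv1. PPP1R15A rose by 1.08 ± 0.10 in 22Rv1 against −0.07 ± 0.10 in PC-3 (adjusted p = 0.75). Of 20 ER chaperones and XBP1 response genes, 4 rose and 5 fell in 22Rv1 (4 and 5 adjusted over the list alone, median 0.00, mean −0.02, camera upward with adjusted p = 0.915). In PC-3 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.04, camera adjusted p = 0.36). SDF2L1 fell by 0.56 ± 0.12 and 0.34 ± 0.12, and EDEM1, a degradation factor, rose by 0.51 ± 0.08 and 0.29 ± 0.08. The synoviolin ligase SYVN1 rose by 0.47 ± 0.05 and 0.17 ± 0.05. HERPUD1 rose by 0.35 ± 0.10 in PC-3 and was 0.07 ± 0.10 in 22Rv1 (adjusted p = 0.61), where it was −0.32 with 0% left out. Of 16 heat shock genes, 14 fell in 22Rv1 (15 adjusted over the list alone, median −0.52, camera adjusted p = 6.85e-07). The largest falls were the chaperones HSPH1 (−1.04 ± 0.12) and HSPA8 (−0.80 ± 0.06), CHORDC1 (−0.63 ± 0.14) and AHSA1 (−0.60 ± 0.09). In PC-3 1 rose and 1 fell (1 and 1 adjusted over the list alone, median −0.06, camera adjusted p = 0.71).

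Genes of mitochondrial metabolism changed in both lines. Of 34 oxidative phosphorylation subunits, 20 fell in 22Rv1 (20 adjusted over the list alone, median −0.15, camera adjusted p = 0.00052, adjusted p = 0.071 with an estimated correlation). In PC-3 12 fell (12 adjusted over the list alone, median −0.09, camera adjusted p = 0.0033, adjusted p = 0.16 with an estimated correlation). In 22Rv1 and PC-3 the succinate dehydrogenase subunit SDHD was at −0.57 ± 0.10 and −0.34 ± 0.10 and cytochrome c (CYCS) at −0.41 ± 0.11 and −0.33 ± 0.11. NDUFA4 fell by 0.37 ± 0.05 and NDUFB3 by 0.33 ± 0.04 in 22Rv1. Of 20 citrate cycle and pyruvate dehydrogenase genes, 10 fell and 3 rose in 22Rv1 (10 and 3 adjusted over the list alone, median −0.19, camera adjusted p = 0.11) and 5 fell in PC-3 (9 fell and 1 rose adjusted over the list alone, median −0.15, camera adjusted p = 0.0068). In 22Rv1 and PC-3 DLAT was at −0.56 ± 0.08 and −0.31 ± 0.08 and IDH3A at −0.51 ± 0.08 and −0.27 ± 0.08. OGDH fell by 0.47 ± 0.07 and IDH2 rose by 0.45 ± 0.09 in 22Rv1. Of 16 mitophagy and autophagy genes, 10 rose and 2 fell in 22Rv1 (10 and 2 adjusted over the list alone, median 0.29, camera adjusted p = 0.0017). In PC-3 7 rose and 3 fell (7 and 3 adjusted over the list alone, median 0.13, camera adjusted p = 0.0033). The mitophagy list shares BNIP3 with the HIF core targets. BNIP3L, a mitophagy receptor, rose by 2.76 ± 0.09 and 1.09 ± 0.09 and MAP1LC3B, which coats autophagosomes, by 0.69 ± 0.07 and 0.28 ± 0.07.

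Cholesterol synthesis genes fell in 9 of 23 cases and rose in 3 in 22Rv1 (9 and 4 adjusted over the list alone, median −0.10, camera adjusted p = 0.14). In PC-3 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.06, camera adjusted p = 0.077). MVK fell by 0.52 ± 0.10 and EBP by 0.43 ± 0.07 in 22Rv1. PMVK fell by 0.41 ± 0.06 in 22Rv1 and 0.23 ± 0.06 in PC-3. Of 21 genes of fatty acid synthesis and lipid storage, 7 rose and 6 fell in 22Rv1 (8 and 6 adjusted over the list alone, median −0.00, mean 0.13, camera adjusted p = 0.35). In PC-3 7 rose and 4 fell (7 and 4 adjusted over the list alone, median 0.10, camera adjusted p = 0.028, adjusted p = 0.27 with an estimated correlation). The lipid droplet genes C7orf68 (HILPDA; 1.43 ± 0.08 and 1.14 ± 0.08) and PLIN2 (1.07 ± 0.08 in both) and the phosphatidate phosphatase LPIN1 (0.71 ± 0.07 and 0.36 ± 0.07) rose in 22Rv1 and PC-3. The acyltransferase GPAM fell (−0.80 ± 0.09 and −0.37 ± 0.09).

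Ribosome biogenesis genes fell in both lines. In 22Rv1 22 of 28 fell and 1 rose (22 and 1 adjusted over the list alone, median −0.39, camera adjusted p = 1.6e-08). In PC-3 20 fell and 2 rose (23 and 2 adjusted over the list alone, median −0.25, camera adjusted p = 2.7e-08, adjusted p = 0.064 with an estimated correlation). RRS1 fell by 1.07 ± 0.12 and 0.64 ± 0.12, NOP16 by 0.93 ± 0.10 and 0.44 ± 0.10 and NIP7 by 0.78 ± 0.08 and 0.45 ± 0.08. RRP12 fell by 0.73 ± 0.08 in PC-3 against −0.08 ± 0.08 in 22Rv1 (adjusted p = 0.45). Ribosomal proteins themselves rose in 7 of 28 cases and fell in 2 in 22Rv1 (5 and 1 adjusted over the list alone, median 0.03, camera adjusted p = 0.16). In PC-3 1 fell (0 adjusted over the list alone, median −0.02, camera adjusted p = 0.69). RPL37 (0.74 ± 0.10), RPL3 (0.26 ± 0.05) and RPL5 (0.25 ± 0.10) rose in 22Rv1, and RPL13 (0.34 ± 0.07) was −0.14 when its probes were averaged. These genes have many near-identical pseudogenes, so single members are uncertain, and the RPL5 call ended under median centring (0.20, adjusted p = 0.24). Of 17 microRNA biogenesis genes, 4 fell in 22Rv1 (4 adjusted over the list alone, median −0.06, camera adjusted p = 0.28). These included GEMIN4 (−0.52 ± 0.05), TARBP2 (−0.45 ± 0.08) and RAN (−0.31 ± 0.04). The Argonaute gene EIF2C2 (AGO2) rose by 0.33 ± 0.10 in PC-3 (1 adjusted over the list alone, median −0.04, camera adjusted p = 0.62).

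Of 20 luminal and epithelial genes, 10 rose and 1 fell in 22Rv1 (10 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.013, adjusted p = 0.18 with an estimated correlation). In PC-3 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.10, camera adjusted p = 0.017, adjusted p = 0.23 with an estimated correlation). In 22Rv1 and PC-3 desmoplakin (DSP) was at 1.22 ± 0.09 and 0.41 ± 0.09 and ELF3 at 0.86 ± 0.12 and 0.96 ± 0.12. The keratins were KRT19 at 0.73 ± 0.07 and 0.39 ± 0.07 and KRT8 at 0.83 ± 0.08 and 0.12 ± 0.08 (adjusted p = 0.31 in PC-3). Of 18 mesenchymal and invasion genes, 6 rose and 1 fell in 22Rv1 (6 and 1 adjusted over the list alone, median 0.06, camera adjusted p = 0.052). In PC-3 5 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.09, camera adjusted p = 0.10). The integrin ITGA5 rose by 1.42 ± 0.15 in PC-3 and was at least 1.92-fold higher in 22Rv1. The matricellular genes CYR61 (CCN1, −0.61 ± 0.11) and CTGF (CCN2, −0.58 ± 0.09) fell in PC-3. Of 9 neuroendocrine genes, 3 rose in 22Rv1 (3 adjusted over the list alone, median 0.06, camera adjusted p = 0.042, adjusted p = 0.086 with an estimated correlation). In PC-3 2 rose (2 adjusted over the list alone, median 0.00, camera adjusted p = 0.089). They were ENO2 (1.76 ± 0.11 in 22Rv1 and 1.66 ± 0.11 in PC-3), which is also a glycolysis gene, together with SCG2 (0.68 ± 0.11) and CALCA (0.61 ± 0.08) in 22Rv1, and FOXA2 (0.43 ± 0.07) in PC-3. The CALCA call ended with 0% left out (0.13, adjusted p = 0.25).

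Immediate early genes rose in 14 of 20 cases in 22Rv1 (15 adjusted over the list alone, median 0.55, camera adjusted p = 7.1e-08). In PC-3 10 rose (12 adjusted over the list alone, median 0.22, camera adjusted p = 8.2e-07, adjusted p = 0.064 with an estimated correlation). FOS rose by 2.29 ± 0.15 in 22Rv1 and was not detected in PC-3, and JUN rose by 1.19 ± 0.12 and 0.90 ± 0.12. KLF4 rose by 0.92 ± 0.13 and 1.24 ± 0.13 and the phosphatase DUSP1 by 0.48 ± 0.08 and 1.20 ± 0.08. Of 26 interferon response genes, 6 rose and 7 fell in 22Rv1 (6 and 7 adjusted over the list alone, median −0.06, mean 0.07, camera downward with adjusted p = 0.96). In PC-3 3 rose and 10 fell (4 and 10 adjusted over the list alone, median −0.13, camera adjusted p = 0.028, adjusted p = 0.31 with an estimated correlation). HLA-B rose by 0.70 ± 0.10 in PC-3. HLA-B and HLA-C were called higher in 22Rv1 as well, but were detected on 2 and 5 of its 12 normoxia arrays, and such close relatives can share signal. IFI6 rose by 0.96 ± 0.13 in 22Rv1, and HERC5 fell by 0.79 ± 0.08 in 22Rv1. Of 18 NF-kB and inflammatory genes, 4 rose and 1 fell in 22Rv1 (3 and 0 adjusted over the list alone, median 0.06, camera adjusted p = 0.11). In PC-3 4 rose and 2 fell (4 and 2 adjusted over the list alone, median −0.04, camera upward with adjusted p = 0.79). They included NFKB2 (0.88 ± 0.10), cyclooxygenase PTGS2 (detected on 3 of 12 normoxia arrays, no size given) and BIRC3 (0.41 ± 0.12) in 22Rv1 and CXCL1 (−0.39 ± 0.12) in PC-3.

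Among 15 genes of the metallothionein and metal handling list, 8 fell and 2 rose in 22Rv1 (9 and 2 adjusted over the list alone, median −0.40, camera adjusted p = 0.14). In PC-3 1 rose and 2 fell (1 and 2 adjusted over the list alone, median −0.07, camera adjusted p = 0.62). MT1G (−0.72 ± 0.13) and MT1F (−0.72 ± 0.13) fell and the ferritin light chain FTL rose (0.84 ± 0.04) in 22Rv1. Metallothioneins are near-identical copies whose probes are uncertain. Of 20 NRF2 and redox genes, 10 fell and 2 rose in 22Rv1 (10 and 2 adjusted over the list alone, median −0.17, camera adjusted p = 0.11). In PC-3 1 rose and 3 fell (1 and 3 adjusted over the list alone, median 0.02, camera adjusted p = 0.95). Heme oxygenase HMOX1 rose (0.92 ± 0.12) and GCLM (−0.64 ± 0.09) and GSR (−0.45 ± 0.08), both of glutathione metabolism, fell in 22Rv1. The ketoreductase AKR1C3 rose in PC-3 (0.79 ± 0.09). Of 17 replication-dependent histones, 5 rose and 4 fell in 22Rv1 (5 and 4 adjusted over the list alone, median −0.07, mean 0.11, camera adjusted p = 0.44). In PC-3 5 rose (5 adjusted over the list alone, median 0.09, camera adjusted p = 0.017, adjusted p = 0.20 with an estimated correlation). HIST2H2BE rose by 1.23 ± 0.11 and 0.42 ± 0.11 and HIST2H2AA3 by 1.04 ± 0.08 and 0.42 ± 0.08 in 22Rv1 and PC-3. Histone genes are close copies, and HIST1H2BD in 22Rv1 (−0.58 ± 0.08) was 0.18 without background correction. Of 8 measured leukocyte markers, 4 rose and 2 fell in 22Rv1 (4 and 2 adjusted over the list alone, median 0.09, camera adjusted p = 0.37). In PC-3 1 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.02, camera adjusted p = 0.62). LCP1 fell (−0.80 ± 0.07) and CD68 rose (0.54 ± 0.08) in 22Rv1. Of 6 fibroblast markers, 3 rose in PC-3 (3 adjusted over the list alone, median 0.11, camera adjusted p = 0.017, adjusted p = 0.14 with an estimated correlation). In 22Rv1 0 passed (0 adjusted over the list alone, median 0.06, camera adjusted p = 0.72). The collagens COL6A3 (0.99 ± 0.10) and COL1A1 (0.62 ± 0.09) led the rises in PC-3. Of the endothelial markers 2 were measured, too few for a test of the list, and 0 passed (1 in PC-3 adjusted over the list alone). ESAM was 0.25 ± 0.10 (adjusted p = 0.058) and PECAM1 0.22 ± 0.14 (adjusted p = 0.28) in PC-3.

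Over the 33 lists tested, 18 passed camera in PC-3 and 17 in 22Rv1, of which 6 and 13 also passed with an estimated correlation. The 6 were the citrate cycle, HIF core targets and, sharing members with these targets, glycolysis, angiogenic factors, collagen modification and mitophagy. A list named above without such a p and past the threshold holds with it. When arrays were regrouped within levels, parting every same-numbered pair, a median of 7 lists passed at the preset correlation in PC-3. In 22Rv1 that median was 10. Regrouped pairs can keep part of the real oxygen effect, so these medians are not those of data without one.

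The oxygen trend asked which genes moved further with each step from 5 to 0% O2. It passed for 272 genes in PC-3 (156 higher and 116 lower as oxygen fell) and 2174 in 22Rv1 (1092 and 1082). In PC-3 ANGPTL4 gained 0.76 ± 0.09 per step (SE, adjusted p = 8.5e-06), the growth factor binder IGFBP3 0.51 ± 0.12, KLF4 0.46 ± 0.08 and ADM 0.46 ± 0.09. HIF1A (−0.42 ± 0.05), the nuclear body gene SP110 (−0.29 ± 0.05), FAM21A (−0.27 ± 0.05), HSPBAP1 (−0.26 ± 0.05), MON1A (−0.25 ± 0.06) and C1orf163 (−0.25 ± 0.05) declined. In 22Rv1 ADM gained 0.77 ± 0.09 per step, the vesicle transport gene RAB31 0.72 ± 0.07, BHLHB2 0.70 ± 0.06, the stress factor ATF3 0.65 ± 0.09 and P4HA2 0.63 ± 0.06. C12orf56 (−0.44 ± 0.06), CDCA7 (−0.41 ± 0.07), BEND3 (−0.40 ± 0.07), CENPA (−0.39 ± 0.04), CCNF (−0.38 ± 0.03) and HSPC111 (NOP16, −0.36 ± 0.05) declined. SCNN1G and C10orf10 in PC-3 and LOX in 22Rv1 passed as well, but their normoxia arrays were mostly at background (2, 4 and 0 of 12 detected), so no slope is given. Under median centring it passed for 206 genes in PC-3 (34 higher, 172 lower) and 784 in 22Rv1 (660 and 124), so the balance of directions depends on the normalization. With 0% left out the counts were 66 and 675. In 22Rv1 the slopes were smaller and the calls ended for ATF3 (0.19, adjusted p = 0.47), CENPA (−0.08, adjusted p = 0.46), CCNF (−0.08, adjusted p = 0.41), C12orf56 (−0.14, adjusted p = 0.42) and HSPC111 (−0.16, adjusted p = 0.22). In PC-3 the slope of C1orf163 was smaller (−0.12, adjusted p = 0.69). With fewer arrays the calls also ended, at slopes close to or beyond those of 6 levels, for IGFBP3 (0.55, adjusted p = 0.14), ADM (0.48, adjusted p = 0.052), SP110 (−0.28, adjusted p = 0.066) and MON1A (−0.31, adjusted p = 0.067). The pair block gave 897 and 3455 genes. The PC-3 count was 110 to 168 without hypoxia 5% replicate 1 (110), normoxia 5% replicate 2 (131), normoxia 0% replicate 2 (132), hypoxia 2% replicate 1 (150), hypoxia 0% replicate 1 (156) or normoxia 2% replicate 2 (168). The calls of IGFBP3 (0.37, adjusted p = 0.18) and MON1A (−0.22, adjusted p = 0.082) ended without a single array.

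The lines were then compared in their response. The mean hypoxia effect differed for 3734 genes, 1838 more positive and 1896 more negative in 22Rv1. RAB31 (3.14 ± 0.17, SE, n = 12 arrays per condition and line, unpaired), BHLHB2 (3.001 ± 0.16) and HLA-H (2.38 ± 0.14) were among the differences upward. MT3, NDUFA4L2, the calcium channel gene CACNA1I and the cytochrome P450 gene CYP1A1 were called upward as well. They were detected on 0 of 24 PC-3 arrays, so no size or rank is given for them. TMEM158 (−1.70 ± 0.12) was among the differences downward. C10orf10, ITPR1, C15orf48 and ADAM8 were called downward but detected on 0 of 24 arrays in 22Rv1, and likewise the integrin ITGB4 (1 of 24), the connexin GJB2 (3 of 24) and OSBP2 (2 of 12 in hypoxia), so no size is given for these. The count was 1949 under median centring (903 and 1046).

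Genes past the threshold in both lines were compared with independent lists. Both lines called 952 genes higher where independent lists would share 347, and 1380 lower where they would share 500, with 111 genes higher in PC-3 and lower in 22Rv1 and 103 the other way. Across genes, which are not independent replicates, the mean effects correlated with r = 0.53 (rho 0.47), and at single levels from 0 to 5% with r = 0.42, 0.44, 0.40, 0.39, 0.31 and 0.19.

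**Figure D4:**
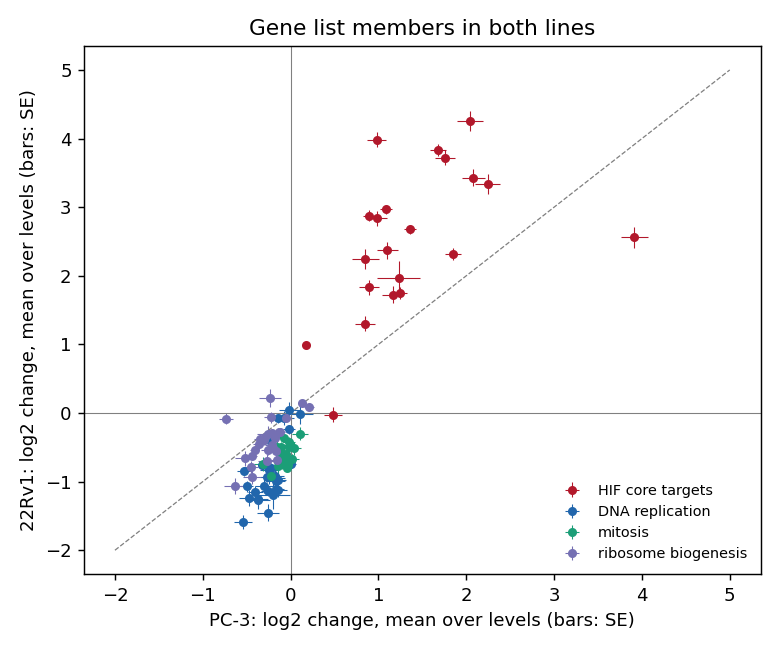
Log2 change over the levels of each member of 4 gene lists in PC-3 (x axis) and 22Rv1 (y axis), with bars for the SE and a dashed line of equal change. HIF core targets (medians 1.16 and 2.56) lie mostly above the line, and DNA replication (−0.23 and −0.94) and mitosis (−0.09 and −0.62) members mostly below it.

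Of the 33 lists, 11 differed in their response between lines. HIF core targets were 1.27 higher in 22Rv1 in the median (18 of 21 genes more positive and 2 more negative, 19 and 2 adjusted over the list alone, camera adjusted p = 4.7e-19). Of the 2 more negative genes, CA9 was not detected in 22Rv1, so its value is set by the floor. The glycolysis median was 0.55 higher (17 and 0, 18 and 0 adjusted over the list alone, camera adjusted p = 1e-16). DNA replication (−0.74, 25 of 31 genes more negative, 27 adjusted over the list alone, camera adjusted p = 5.1e-17) and mitosis (−0.54, 25 of 27, 26 adjusted over the list alone, camera adjusted p = 1.9e-17) were more negative. So were homologous recombination and mismatch repair (−0.36, 12 of 22, 13 adjusted over the list alone, camera adjusted p = 8.7e-07) and heat shock (−0.45, 11 of 16, 14 adjusted over the list alone, camera adjusted p = 1.1e-07). The p53 targets were more positive (0.17, 6 of 20, 6 adjusted over the list alone, camera adjusted p = 0.0043). Another 4 lists passed with the preset correlation but not with an estimated one. They included histone demethylases (0.24, 4 genes, 5 adjusted over the list alone, adjusted p = 0.37 with an estimated correlation) and cholesterol synthesis (−0.18, 7 lower and 1 higher, likewise adjusted over the list alone, adjusted p = 0.43 with an estimated correlation). Ribosome biogenesis (−0.14, 7 lower and 1 higher, 9 and 2 adjusted over the list alone, adjusted p = 0.49 with an estimated correlation) was another of them.

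In normoxia the lines differed at 11801 genes, 6452 higher in 22Rv1 and 5349 higher in PC-3, and 3805 of them at least 2-fold. Higher in 22Rv1 were the prostate kallikrein KLK4 (at least 132-fold), the cancer-testis genes XAGE1A (at least 83.2-fold), XAGE1B (at least 73.9-fold), CTAG2 (at least 59.3-fold) and MAGEA1 (at least 46.9-fold), the adhesion gene CTNNA1 (at least 71.2-fold) and PAFAH1B3 (at least 63.9-fold). XAGE1 was higher in 22Rv1, without a size, since 1 of 12 normoxia arrays of PC-3 detected it, and its near-identical copies make the XAGE1 values uncertain. Higher in PC-3 were MSMP (at least 393-fold), the keratin KRT81 (at least 328-fold), the protease inhibitor PI3 (at least 212-fold), the proteoglycan SRGN (at least 183-fold), the caveolin CAV1 (at least 145-fold) and PHACTR3 (at least 119-fold). The Wnt antagonist DKK1 and the retinoic acid enzyme ALDH1A3 were higher in PC-3 as well, without a size, since 2 and 1 of 12 normoxia arrays of 22Rv1 detected them. The kallikrein KLK2 was at least 1.34-fold higher in 22Rv1. KLK3, the gene of prostate-specific antigen, was not detected on enough arrays to be tested.

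Among the 6 normoxia control groups of a line, limma called 0 genes in PC-3 (283 at an unadjusted p under 0.05) and 0 in 22Rv1 (557 at an unadjusted p under 0.05). Without the filter on dim probes the counts were 1 and 4. A replicate block over the line gave 1 in PC-3 and 0 in 22Rv1, with 516 and 942 at an unadjusted p under 0.05. The unadjusted counts without a block are fewer than uniform p-values would give. On simulated data the PC-3 test recovered 4% of shifts of 0.5 (log2) in 1 control group and 74% of shifts of 1. The 0 calls therefore do not show that the control groups were alike.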

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

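The tests of the labels of the doubted pair, of the 0.2% and 0.5% levels and of the 0% level were chosen after the results were seen, except the test of quantile normalization on the ATF4 list. So were the test of exchanged pairs on the line difference and the comparisons between levels. The difference of the mean hypoxia effect between the lines was tested in the planned model and passed for 3734 genes, in 22Rv1 minus PC-3. With each line centred first, so that the lines' baseline difference takes no part, 1 of 100 exchanges of pairs between the lines within levels gave as many (the real one, highest other 1772), so chance can be excluded.

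Among genes named above, the difference in log2 was positive for ADM (2.21), PFKFB4 (2.15), SLC16A3 (1.98), BNIP3 (1.89), P4HA1 (1.85), JMJD1A (1.39), DDIT4 (1.35), PFKFB3 (1.32), VEGFA (1.27), NDRG1 (1.09), ERO1L (0.94) and LDHA (0.83). It was also positive for ANKZF1 (0.57), INSIG2 (0.50), SLC2A1 (0.47) and MXI1 (0.45). Others were RAB31 (3.14), BHLHB2 (3.001) and HLA-H (2.38), and of the genes that fell in PC-3 ID3 (0.81), HIF1A (0.79) and FLJ38482 (0.43). It was negative for TMEM158 (−1.70) and ANGPTL4 (−1.35). Of the genes that fell in 22Rv1 it was negative for UHRF1 (−1.33), CCNE2 (−1.19), CDC25A (−1.13), POLE2 (−1.04), CDCA7 (−1.0011), CHAF1B (−1.0013), MIR1978 (−0.97), RRM2 (−0.90), GINS2 (−0.88), MCM10 (−0.77) and TIPIN (−0.51). For the following genes a side of the comparison was mostly not above background, so the fitted values are set by the floor and give no size or rank. In PC-3 0 of 24 arrays detected MT3 (4.09), NDUFA4L2 (3.46), CACNA1I (2.43), CYP1A1 (2.30) and FLJ12684 (−1.42). In 22Rv1 0 of 24 detected C10orf10 (−2.05), ITPR1 (−1.97), C15orf48 (−1.63), ADAM8 (−1.63) and CA9 (−0.50), and 7, 3 and 1 detected C14orf126 (0.68), GJB2 (−1.597) and ITGB4 (−1.55). In 22Rv1 hypoxia 2 of 12 detected OSBP2 (−1.94). In 22Rv1 normoxia 0 of 12 detected PPFIA4 (2.15), ANKRD37 (1.96) and SCNN1G (−1.05). The list medians that differed included, upward, HIF core targets (1.27), glycolysis (0.55) and p53 targets (0.17). Downward were DNA replication (−0.74), mitosis (−0.54), heat shock (−0.45) and homologous recombination and mismatch repair (−0.36). Histone demethylases (0.24), cholesterol synthesis (−0.18) and ribosome biogenesis (−0.14) differed at the preset correlation but did not pass with an estimated one.

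The tables give opposite labels to the 22Rv1 replicate 2 arrays at 0.2% O2. By the intensity table's names the HIF core targets of this pair differ by 2.30 in the mean, upward in hypoxia, which argues against an exchange in that table. The value lies below the 2.66 to 3.64 of the other 22Rv1 pairs at 0 to 1%. By the other table's labels the difference is −2.30, against the direction of every other 22Rv1 pair at those levels, so an exchange of labels in the other table is the open explanation. No biological explanation was tested.

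More genes changed at 0.5% than at 0.2% O2 in 22Rv1 (4611 against 1801), although 0 genes differed between the levels in limma (1436 at an unadjusted p under 0.05). Over 1452 genes called the same way at 0% and 1%, the replicate 1 pair at 0.2% has a median change of 0.876, within the 0.833 to 1.11 of the 0.5% pairs. The doubted pair has 0.472, so a weaker response in that pair may account for part of the lower count. Without that pair the counts are 2057 at 0.2% and 4947 at 0.5%, so the gap stays, with 1 array against 1 at 0.2%. With 1 pair at each level, 0.2% replicate 1 gives 2442 or 2443 genes, against 4626 for replicate 1 and 1881 for replicate 2 at 0.5%, so the gap depends on the pair. Dim arrays stay open, with 15081 probes detected on average at 0.2% against 15116 to 15424 at other levels. That gap is small beside the spread within a level, 14446 to 15758 at 0.2%. Arrays at 0% (13995), 0.5% (14393) and 5% (14386) reached lower, so the detected probes show no clear dimness at 0.2%. Exchanged level labels stay open as well, with a gap of −0.0428 between the smallest response at 0.5% and the largest at 0.2%. A biological difference between the levels is untested.

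At 0% O2 22Rv1 stood apart from 0.2 to 1%, with 2169 genes differing. The ATF4 list has a median of −0.312 at 0.2 to 1% and 1.29 at 0%, which argues against a larger dose of the same response for that list. The HIF core targets moved as a larger dose would. Their mean difference was 3.64 and 3.57 in the pairs at 0% against 2.30 to 3.13 in those at 0.2 to 1%. For the other genes a larger dose stays open. On average 15177.5 probes were detected at 0%, within the 15081 to 15424 of the other levels. Hypoxia replicates 1 and 2 at 0% detected 14699 and 16494 probes, and normoxia replicate 2 detected 15522. Dim arrays stay open, since a normoxia array at 0% (replicate 1) detected 13995 probes against 14386 to 16146 on 22Rv1 arrays of other levels. Without it the count is 1471. Under median centring 39.1% of the 2169 genes stay called, with a median change of 0.848 (SE 0.296) against 0.862 (SE 0.209). The median change was 1.01 against 0.918 for the higher genes and 0.675 against 0.824 for the lower ones. Calls ended with the larger SE, and of the calls at 0% O2 35.9% stayed in PC-3 and 56.8% in 22Rv1, so it stays open whether quantile normalization adds to the count. For the ATF4 list 1.71 against 1.45 argues against it. A biological effect of 0% oxygen is untested and stays open.

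Other splits of the arrays within levels that part every same-numbered pair were counted for the planned comparisons. Of 100 splits, 1 gave as many genes as the PC-3 mean over levels (3946, highest other 2070) and 1 as many as the 22Rv1 mean (7007, highest other 5324), so chance can be excluded for both. As many lists as in PC-3 (18) came from 3 of 100 splits, the real one included. Another split passed more lists (19), so chance is made less likely but is not excluded. As many as in 22Rv1 (17) came from 13 of 100 (highest other 19), so chance cannot be excluded there either. For the lines in normoxia 1 of 100 exchanges gave as many genes (11801, highest other 9032). Over the splits that part every pair the median was 0 genes in PC-3 and 1 in 22Rv1. For the lists the median was 7 in PC-3 and 10 in 22Rv1. A split can leave many pairs with their real labels, so part of the oxygen effect can stay in its mean. The list counts of the splits are therefore not those of data without an oxygen effect, and they cannot decide about chance. In simulated data with independent noise and a shift in the mitosis list only, 0 other lists were called. Splits of any kind within levels reached at most 351 and 5604 genes and 20 and 21 lists. As many as in the real split came from 1, 1, 2 and 10 of 100, the real one included.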

How the results depend on the processing

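The alternatives that use other labels for the doubted pair or leave it out were chosen after seeing the data. Of 426 named gene values, 419 kept direction and side of the threshold without background correction, 402 under median centring, 385 in the other table, and 420 without a filter. They were 422 of 422 with the 12-array filter, 419 with the mean of probes, 369 of 378 with each line alone, and 422 with pooled controls. With the pair block they were 395 of 408, with a block over the line 419, and 423 without a variance trend, 419 with array weights. They were 390 with the doubted pair labelled as in the other table, 419 in the other table with the intensity table's labels and 424 without the doubted pair. The other table ranks the probes of an array as the intensity table does. With the intensity table's labels it is therefore hardly a separate check from the setting without background correction. With 0% left out 14 of 24 trends and 286 of 306 means were kept, with log2 oxygen 14 of 24 trends, and 401 held on every left-out array. Reversals were HIST1H2BD in 22Rv1 (−0.58; 0.18 without background correction, 0.16 in the other table, 0.19 there with the intensity labels), RPL13 in 22Rv1 (0.34; −0.14 with the mean of probes) and HERPUD1 in 22Rv1 (0.07; −0.32 over 5 levels). The cause was not tested for any change below except where fewer arrays, or more controls, made it by construction. Signal over background limits dim genes, and single levels rest on 2 arrays against 2.

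Left-out arrays gave, for PC-3 from 0 to 5%, 574 to 904, 267 to 474, 252 to 369, 58 to 107, 10 to 40 and 0 to 3 genes. For its mean they gave 3449 to 3838, its trend 110 to 335, its lists 17 to 20 and its controls 0 to 0. For 22Rv1 they gave 3478 to 3932, 430 to 3249, 2015 to 5132, 1079 to 1751, 175 to 446 and 3 to 35. For its mean they gave 6534 to 7399, its trend 1701 to 2727, its lists 16 to 18 and its controls 0 to 1 (1 without normoxia replicate 2 of 0.5, 1 or 2%). The line difference was 3456 to 4325 and normoxia 11647 to 11725. With 1 array left in a group, the lone sample is assumed to vary like the other groups.

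Median centring gave in PC-3 524 (253 higher, 271 lower) at 0%, 212 (178, 34) at 0.2%, and 884 (73, 811; 397 and 273 with quantile normalization) at 0.5%. It gave 44 (42, 2) at 1%, a mean of 2286 and a trend of 206 (34, 172). In 22Rv1 it gave 2739 (1553, 1186) at 0%, 638 (404, 234) at 0.2% and 2595 at 0.5%. It also gave 1063 at 1%, 232 (225, 7) at 2%, 2 at 5%, a mean of 5663 (2089, 3574) and a trend of 784 (660, 124), and 1949 for the line difference. It moved the median of all genes by −0.29 at 0.5%, 0.10 at 2% and 0.21 at 5% in PC-3 and by −0.20 at 5% in 22Rv1, so those counts are relative to that shift. Array weights gave in PC-3 2227 at 0%, 1204 at 0.2%, 415 at 1%, 132 at 2%, 22 (19, 3) at 5% and a trend of 648 (304, 344), and in 22Rv1 584 (415, 169) at 0.2% and 3019 at 0.5%.

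The other table gave in PC-3 485 at 0.2%, 403 at 0.5%, 102 at 1%, 18 at 2% and a trend of 169. In 22Rv1 limma called 0 at 0.2% (695 at an unadjusted p under 0.05), 28 at 2%, 0 at 5% (515 at an unadjusted p under 0.05) and a trend of 1100. With the intensity table's labels it gave 3 in PC-3 and 8 in 22Rv1 at 5%, the counts also found without background correction. With the doubted pair labelled as in the other table, PC-3 had 424 at 0.2%, 369 at 0.5%, 64 at 1%, 10 at 2%, 0 at 5% (574 at an unadjusted p under 0.05) and a trend of 130. In 22Rv1 limma called 0 at 0.2% (712), 34 at 2%, 0 at 5% (542) and a trend of 1095. Without that pair PC-3 had 79 at 2% and 4 at 5%.

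Pooled controls gave in PC-3 3409, 2056, 1984, 1050, 375 and 122 from 0 to 5% and a trend of 1297. In 22Rv1 they gave 3651 at 0.2%, 6924 at 0.5%, 4573 at 1%, 1951 at 2%, 126 at 5% and a trend of 4432. The pair block gave in PC-3 2647, 1770, 1642, 682, 213 and 57 and a trend of 897. In 22Rv1 it gave 3272 at 0.2%, 3944 at 1%, 1969 at 2%, 50 at 5% and a trend of 3455. The block over the line gave in PC-3 1318 at 0.2%, 1163 at 0.5%, 440 at 1%, 130 at 2%, 17 at 5%, a trend of 540 and 1 for the controls, and in 22Rv1 1276 at 2% and 32 at 5%. Each line alone gave in PC-3 1170 at 0.2%, 1024 at 0.5%, 363 at 1%, 86 at 2% and a trend of 509, and in 22Rv1 1062 at 0.2%, 1565 at 1%, 280 at 2% and 3 at 5%.

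At 5% PC-3 had 4 genes with the 12-array filter, 8 with the mean of probes and 3 without a variance trend, and without a filter the controls had 1 and 4. The trend with 0% left out gave 66 and 675, and with log2 oxygen 65 and 608. With an estimated correlation 6 lists passed in PC-3, and with fry 30 in 22Rv1. A block by slide was not run, since no slide is given, and the pair block for normoxia and controls and pooled controls for the controls give no value.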

Other observations

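The comparisons between levels in this part were chosen after the results were seen. Against its own control at 0% O2 in 22Rv1, the stress factor ATF3 rose by 4.14, GDF15 by 4.47, the C/EBP homologous protein gene DDIT3 by 3.01 and CDKN1A by 2.41, while the mitotic genes CCNB1 (−2.37) and PLK1 (−1.89) fell. Of 26 ATF4 genes 20 rose and 1 fell at 0% (20 and 1 adjusted over the list alone, median 1.29, camera adjusted p = 8.7e-16). Of 20 ER chaperones 17 rose (17 adjusted over the list alone, median 0.95, camera adjusted p = 2.8e-10). Of 20 p53 targets 14 rose (14 adjusted over the list alone, median 1.08, camera adjusted p = 6.7e-11), and of 27 mitosis genes 27 fell (27 adjusted over the list alone, median −1.76, camera adjusted p = 8.3e-32). In PC-3 at 0% the values were 0.80 for DDIT3 and 1.57 for CDKN1A.

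Set against 0.2 to 1% in the same line, 2169 genes differed at 0% in 22Rv1 (1097 higher, 1072 lower) and limma called 0 in PC-3 (482 at an unadjusted p under 0.05, 160 with pooled controls, 1 without hypoxia 0.2% replicate 1). The 22Rv1 count was 3376 with the pair block, 4403 with pooled controls, 850 under median centring (642 higher, 208 lower) and 1409 without hypoxia 0% replicate 1. ATF3 was 3.56 ± 0.44 higher at 0%, DDIT3 3.29, the ER chaperone cofactor DNAJB9 2.99 and PHLDA3 2.60. HERPUD1 was 2.55, GDF15 2.54 and PSAT1, of serine synthesis, 2.23 higher. CENPA was −2.33 and PLK1 −1.88. Of 33 lists 14 passed camera on this step in 22Rv1 (4 with an estimated correlation) and 8 in PC-3 (0 with it). The lists ATF4 (21 higher, median 1.45, camera adjusted p = 1.9e-28) and ER chaperones (18 higher, 19 adjusted over the list alone, median 1.45, camera adjusted p = 1.4e-22) also passed with an estimated correlation. So did p53 targets (14 higher, median 1.16, camera adjusted p = 2.6e-14) and mitosis (26 lower, 27 adjusted over the list alone, median −1.29, camera adjusted p = 3e-33). This step differed between the lines for 785 genes (447 and 338), 1614 with the pair block, 2683 with pooled controls, 154 under median centring. It was 516 without PC-3 normoxia 0% replicate 2 and 522 without PC-3 hypoxia 0% replicate 1.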
